A study of Caenorhabditis elegans with 2 samples.

How the data were processed

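The measurements are anti-GFP ChIP-seq libraries from whole late embryos of C. elegans strain OP517, which expresses SOX-4 fused to GFP and FLAG, collected 4 hours after synchronization. The labels give 2 biological replicates of 1 group, with sonicated chromatin and 1 library each, sequenced on Illumina HiSeq instruments. Replicate numbers were taken from the labels.

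The processed files are lists of regions in narrowPeak format on the builds ce10 and ce11. Per the descriptions deposited with each library, a list of peaks and background was called on each replicate's alignments and another on both libraries pooled. Each was called against a control alignment. A thresholded list was made from them by the irreproducible discovery rate (IDR), which rates how alike regions rank in replicates. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal value of each region, as the authors deposited it, is the peak caller's own measure of strength relative to the control alignment. It was not scaled between libraries, so it was used to describe and rank regions within a list. The 668 thresholded peaks on ce11 were the 668 strongest regions of the pooled list, so the threshold acts as a minimum signal of 130 in that list. A single peak in the list was therefore not kept for its own agreement between replicates. Because a control alignment was already used by the authors and no control list was used here, background that the control did not remove cannot be measured from these lists. Closely repeated sequence, such as tRNA genes, is affected by how the aligner treated reads with several matches, which is not given in the sources used here.

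The lists hold no read counts, so the depth of each library and the sampling error of each signal value are unknown. Intervals on shares of peaks are Wilson 95% intervals and cover counting error over peaks only. Peaks are not independent replicates, and tests over peaks describe these 2 libraries.

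All main results use ce11. Gene models were those of Ensembl release 115 for WBcel235, the same assembly as ce11, and sequence came from the RefSeq copy of that assembly, and every listed region ended within its chromosome. The ce10 lists, with 684 thresholded peaks, served only as alternatives that need no annotation of ce10. Coordinates are given from 1. A peak's position is its summit.

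Replicate agreement was the share of the strongest 668 regions of replicate 1 that overlap one of the strongest 668 of replicate 2 by 1 bp or more, against 1000 random placements within chromosomes (one-sided). Shares of summits in promoters, other gene parts and within 200 bp of non-coding genes were compared with 10000 random placements within chromosomes (two-sided, smallest p 0.0002). Gene lists were tested by Fisher's exact test (two-sided) on the nearest protein-coding 5' end within 2000 bp, with genes near any region of the pooled list as background. There were 19 lists, fixed before the data were examined: pan-neuronal genes, neural transcription factors, ciliated sensory neurons, body wall muscle, pharynx, intestine, epidermis and cuticle, glia, germline, early fate and mesoderm regulators, the SOX family, stress response, cytosolic ribosomal proteins, histones, collagens, and the ceh, nhr, hlh and tbx gene families. In 5 lists a total of 6 listed symbols matched no protein-coding gene. A set of 16 consensus sequences, also fixed beforehand, and all 6-mers were scored as present or absent on either strand within 50 bp of the summit and in a flank 300 bp to the left or right in alternation, with an exact McNemar test (two-sided). Chromosome shares were tested by an exact binomial test (two-sided). Peaks within 20 kb of sox-4 and unc-119 were counted against 10000 draws of protein-coding genes from all 6 chromosomes (one-sided). Adjusted p-values are Benjamini-Hochberg values within each family, with a threshold of 0.05. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

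The genes named were chosen by a rule set before the data were examined: the nearest protein-coding 5' end within 2000 bp of each of the 25 strongest peaks, the 4 members with the largest signal for a list past the threshold and the 2 largest for other lists, every SOX family member with a peak, the 5 6-mers with the smallest p, and sox-4 and unc-119 whatever their value. The non-coding genes named at peaks, and the 6-mers more frequent at summits, were chosen after their values were seen.

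The procedures were tested on simulated data. In 20 sets of random positions, 0 reached p under 0.05 for promoters or for the SOX consensus and 0 6-mers were called. In 20 draws of 668 pooled regions 0 gene lists were called. Random positions lack the GC difference between summits and flanks given below, so these sets cannot show calls that come from composition. For promoters they were drawn in the same way as the random placements of the test itself. Moving 100 positions to promoters raised the promoter count from 73 to 160, and moving 100 to tRNA genes gave 103 tRNA peaks. Writing 134 SOX sites into windows raised the count from 113 to 222, and all 300 planted shared regions were found. These planted cases check the counting only. Alternatives were set beforehand for the peak set (the stronger 334 peaks, and the strongest 668 regions of each replicate alone), the overlap rule, the promoter window, the gene background, the assignment distance, the window width, the flank distance, the expected share of a chromosome, the window around the transgene loci and the build. Those chosen after seeing the data leave out the 253 peaks near tRNA, snRNA, snoRNA, rRNA or microRNA genes, or take the control sequence from weaker pooled regions matched on GC content.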

Results

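Chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which DNA bound by a protein is recovered with an antibody and sequenced, was used to locate the transcription factor SOX-4 on the genome of Caenorhabditis elegans. SOX-4 belongs to the SOX proteins, which contact DNA through an HMG box and are known as regulators of cell fate. The worms were of strain OP517, which carries an integrated transgene for SOX-4 with GFP and FLAG at its C terminus, and the antibody was directed against GFP. Whole late embryos of mixed sex were collected 4 hours after synchronization by bleaching. The series held 1 group of 2 biological replicates with 1 library each. No sample without the tagged protein was analysed here, so the comparisons are between the replicates, and between the peaks and random positions, flanking sequence or weaker regions of the same genome. The thresholded list held 668 peaks on build ce11, with a median width of 416 bp and signal values from 130 to 1365 (median 177). Each replicate's own list and the list from the pooled libraries held 30000 regions, weak ones included. The lists give no read counts, so the sequencing depth of each library is unknown.

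The first question was whether the replicates had their strongest regions at the same sites. The 6 strongest peaks all lay within 200 bp of small nucleolar RNA (snoRNA) genes, whose products guide the modification of other RNAs. They were at C51F7.3 and C51F7.4 (chromosome V, 12303442 to 12303826, signal 1365), W03C9.9 (II, 11960638 to 11961019, signal 1278), ZK994.7 (V, signal 1051), ZK265.10 (I, signal 1050), T06C12.16 (V, signal 1018) and T03F7.8 (V, signal 947). The peak over snoRNA genes C51F7.3 and C51F7.4 ranked 1 in replicate 1 and 2 in replicate 2, and the peak at W03C9.9 ranked 2 and 1. Among the 25 strongest peaks, 13 lay near a snoRNA gene and 4 near a tRNA gene, and all 25 ranked 44 or better in each replicate. Peaks in promoters of protein-coding genes reached the same range at atx-2 (III, 10461156 to 10461475, signal 712), a homologue of the RNA-binding protein ataxin-2, at ears-2 (IV, 390357 to 390627, signal 663), a mitochondrial glutamyl-tRNA synthetase, and at idhg-1 (III, 4568614 to 4568874, signal 653), a subunit of isocitrate dehydrogenase.

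Of the 668 strongest regions of replicate 1, 425 overlapped one of the 668 strongest of replicate 2 by 1 bp or more. That share of 63.6% (Wilson 95% interval 59.9 to 67.2) compared with a mean of 0.553% and a maximum of 2.096% over 1000 random placements within chromosomes. The one-sided permutation p was 0.001, the smallest those placements can give. Random placements ignore enrichment that any pulldown would share, so the overlap shows shared regions and not that SOX-4-eGFP was bound there. All 668 thresholded peaks had a region in the list of replicate 1, and 654 (97.9%) had one in the list of replicate 2. Among the 668 strongest regions of both replicates stood 419 peaks (62.7%). Across those 654 peaks, which are not independent replicates, the signal values of the replicates had a Spearman rho of 0.69. The peaks were the strongest regions of the same 2 libraries pooled, and each replicate's list holds 30000 regions. The counts over peaks, this rho and the replicate ranks of the 25 strongest peaks above are therefore partly set by that choice. The share of peaks that stood among the 668 strongest regions of both replicates was 90.9% of 55 snoRNA peaks (median signal 371), 76.8% of 185 tRNA peaks (median signal 217) and 63.9% of 180 promoter peaks with no RNA gene nearby (median signal 179). It was 41.2% of the 148 peaks near no RNA gene and outside promoters (median signal 149). These shares had the order of the median signals, and the groups were not compared at equal signal.

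**Figure D1:**
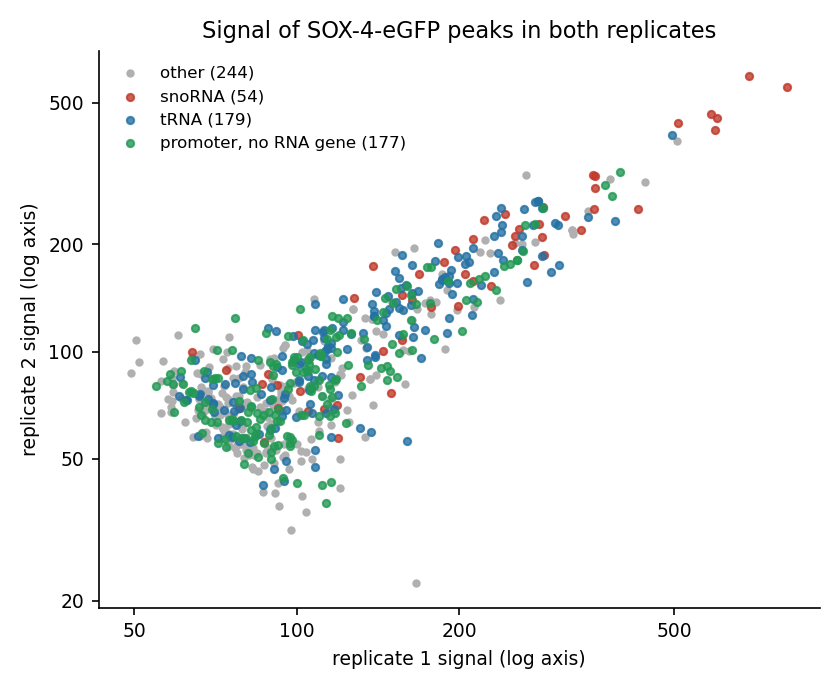
Signal value of each of the 654 peaks found in both replicates' lists, replicate 1 on the horizontal and replicate 2 on the vertical log axis, coloured by the annotation near the summit, with the number of peaks per class in brackets. The 6 peaks with the largest pooled signal, in the upper right corner, are near snoRNA genes, and Spearman's rho over all points is 0.69.

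The next comparison asked which classes of non-coding gene carried peaks. Transfer RNA genes carried the largest named group: 185 peaks (27.7%, Wilson interval 24.4 to 31.2) had their summit within 200 bp of one, where random placements gave a mean of 2.12, a ratio of 87.2. Peaks near snoRNA genes numbered 55 against 1.197 by chance (45.9-fold), those near small nuclear RNA (snRNA) genes 9 against 0.368 (24.4-fold), and those near microRNA genes 5 against 0.841 (5.95-fold). Unclassified ncRNA genes, which often overlie the named RNA genes in this annotation, had 231 peaks nearby against 24.9 (9.28-fold). Peaks were scarcer than chance near piRNA genes, with 4 against 16.195, and near pseudogenes, with 6 against 23.7 (0.254-fold). In the strongest 668 regions of replicate 1 alone, 10 lay near pseudogenes (0.417-fold, still past the permutation test). Counted by gene, 197 of 612 tRNA genes (32.2%), 56 of 346 snoRNA genes (16.19%), 8 of 129 snRNA genes (6.20%) and 5 of 261 microRNA genes (1.92%) carried a peak. The summit fell inside the tRNA gene in 129 of the 185 tRNA peaks (69.7%). Examples were C04A11.t1 on X (13665393 to 13665759, signal 906), T21B4.t1 on II near the collagen gene col-85 (signal 616), C37A2.t1 on I (signal 582) and F17H10.t1 on X (signal 548). The strongest peak near an snRNA gene was at R07E5.16 on III (signal 535), and the strongest near a microRNA gene at mir-51 on IV (signal 578).

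In all, 7 of 9 classes passed an adjusted p of 0.05 in the two-sided permutation test of 10000 placements with Benjamini-Hochberg adjustment. The adjusted p was 0.0003 for tRNA, snoRNA, snRNA, unclassified ncRNA, piRNA and pseudogene, each from the smallest p the placements can give, and 0.00566 for microRNA. Long intergenic RNA genes had 4 peaks against 2.16 (adjusted permutation p = 0.392), and ribosomal RNA genes had 0 against 0.0992 (adjusted permutation p = 1). The ratios depended on the distance allowed: with the summit inside the gene they were 355 for tRNA, 15.9 for snoRNA and 35.6 for snRNA, within 500 bp they were 41.96, 22.5 and 11.9, and in the stronger 334 peaks they were 119.6, 74.3 and 42.6, all past the permutation test. The microRNA class did not pass in the stronger 334 peaks (2 peaks, 4.87-fold, adjusted permutation p = 0.170). With the summit inside the gene, neither the microRNA class (0 peaks, adjusted permutation p = 1) nor the piRNA class (0 peaks, adjusted permutation p = 0.894) passed.

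**Figure D2:**
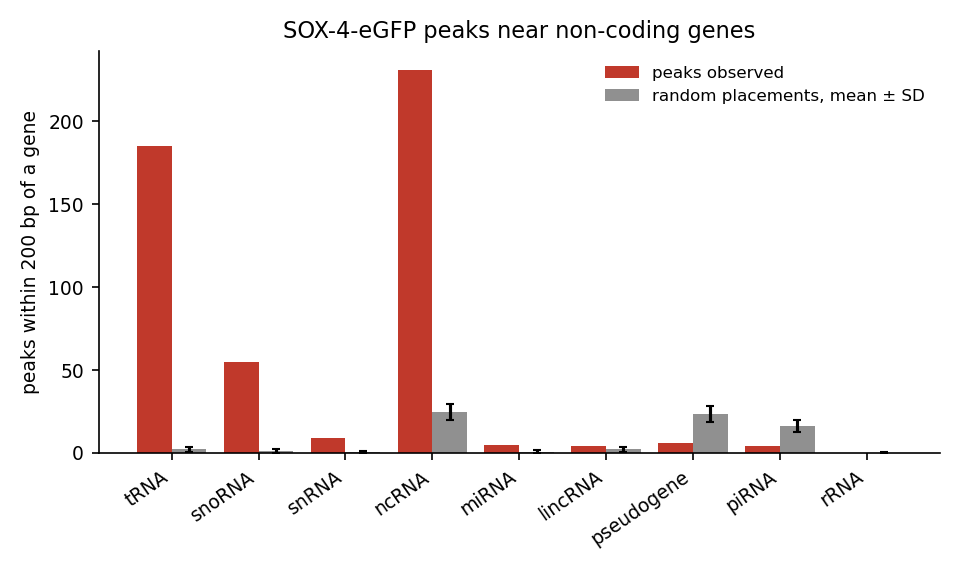
Number of the 668 peaks with the summit within 200 bp of a gene of each non-coding class (dark bars) and the mean and SD over 10000 random placements (grey bars with error bars). The tRNA bar stands at 185 against 2.12 and the snoRNA bar at 55 against 1.197, while pseudogenes and piRNA genes lie below their random means.

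Promoters of protein-coding genes held 239 of the 668 summits, counted from 500 bp upstream to 100 bp downstream of an annotated 5' end. The share of 35.8% (Wilson interval 32.2 to 39.5) was 3.29 times the 10.9% of random placements (SD 1.21 percentage points, two-sided permutation p = 0.0002, the smallest possible). Coding exons held 12 summits, 1.80% against 22.5% by chance, and 3' untranslated regions 4 summits, 0.599% against 2.86% (both permutation p = 0.0002). In the same permutation test, introns held 30.1% against 32.9% (p = 0.128), intergenic sequence 31.3% against 30.1% (p = 0.535) and 5' untranslated regions 0.449% against 0.753% (p = 0.517), and none of these 3 passed the test. Among the 25 strongest peaks, 19 had a protein-coding 5' end within 2000 bp. The nearest such genes were atx-2, ears-2, idhg-1, T13C5.6, F55A11.11 and T02E1.2 at distances inside the promoter window, and K12H4.5 and the chemoreceptor gene sre-23 somewhat further upstream. For the other 11 the summit lay downstream of the 5' end: F55C5.17, W03C9.1, str-56, C04A11.5, the kinase gene mpk-2, Y43F8C.7, the mRNA cleavage factor gene cfim-2, col-85, the potassium channel gene twk-5, the cyclin E gene cye-1 and the sorting nexin gene snx-17. Of these 19 genes, those next to a tRNA or snoRNA gene share the peak with it, and the lists do not assign the peak to either.

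Gene groups fixed beforehand were then tested for peaks near their members. Within 2000 bp of a protein-coding 5' end lay 458 peaks (68.6%), which named 447 genes out of 9804 that had any region of the pooled list. Cytosolic ribosomal protein genes carried peaks more often than other genes: 9 of 57 members (15.8%) against 4.49% of the rest, an odds ratio of 3.99 (Fisher's exact p = 0.00100, adjusted p = 0.0191 over 19 lists by Benjamini-Hochberg). The strongest were rpl-3 (III, 3867441 to 3867721, signal 536), rpl-15 (IV, 654827 to 655045, signal 347), rpl-35 (III, 7854512 to 7854927, signal 293) and rps-28 (IV, 1659041 to 1659456, signal 280), all with summits 286 to 442 bp upstream of the 5' end. With background regions matched on distance to the 5' end the ratio was 3.05 and the adjusted p 0.0759, and with assignment within 5000 bp the adjusted p was 0.0649, so the call did not survive these 2 settings.

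The other 18 lists did not pass (Fisher's exact test, adjusted p = 1 for each). Neural transcription factors had 3 of 30 members with a peak, among them daf-19 (signal 293), which encodes the regulator of cilium genes, and the homeobox gene ceh-2 (signal 137, at a tRNA gene). The glial list had the glutamate transporter gene glt-1 (signal 197) as 1 of 8, the stress list the chaperone gene hsp-1 (signal 188) as 1 of 20, and the histone list his-68 (signal 197) as 1 of 16. Collagen genes had 6 of 99, led by col-85 (signal 616, at a tRNA gene) and col-94 (signal 535, at an snRNA gene). Nuclear hormone receptor genes had 3 of 120, led by nhr-255 (signal 427, at a tRNA gene) and nhr-88 (signal 143). Homeobox genes named ceh had 1 of 45, again ceh-2, and helix-loop-helix genes 1 of 10, hlh-11 (signal 148), which ranked 345 in replicate 1 and 2804 in replicate 2. No member carried a peak among pan-neuronal genes (22 members in the background), ciliated sensory neuron genes (15), body wall muscle genes (26), pharynx genes (13), intestine genes (9), epidermis and cuticle genes (33), germline genes (20), early fate and mesoderm regulators (28), T-box genes (8) and the SOX family itself (3).

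The sequence under the summits was compared with windows of the same width centred 300 bp away, taking 50 bp to either side of each summit. The SOX consensus WWCAAWG was present in 47 of 668 summit windows, 7.04% (Wilson interval 5.33 to 9.23), and in 14.7% of flanking windows (12.2 to 17.6), so it was rarer at summits by an odds ratio of 0.452 (exact McNemar p = 1.35e-05, adjusted p = 7.18e-05 over 16 consensus sequences). The GATA consensus WGATAR fell from 20.96% in flanks to 8.83% at summits, and the homeodomain core TAATTA from 5.39% to 1.35%. The TCF consensus CTTTGWW fell from 8.38% to 4.04% and the forkhead consensus TRTTKRY from 28.3% to 20.8%. Their adjusted p lay between 9.38e-09 and 0.00386 in the same exact test. Every TCF match is also a SOX match, because its reverse complement WWCAAAG is a form of WWCAAWG, so the 2 results are not separate. The homeodomain odds ratio of 0.229 became 0.441 without replicate 2 and 0.150 without replicate 1. That of TCF went from 0.473 to 0.423 and 0.262, all past the exact test. The forkhead difference did not pass without replicate 2 (odds ratio 0.800, exact test, adjusted p = 0.169), with 25 bp to either side (0.743, adjusted p = 0.225) or with flanks 600 bp away (0.805, adjusted p = 0.189). Without the peaks near structural RNA genes, neither the forkhead (0.717) nor the homeodomain difference (0.421) passed (exact test, adjusted p = 0.119 for both). The GC-rich SP1/KLF box GGGCGG rose from 1.80% in flanks to 9.73% at summits (odds ratio 6.30, exact McNemar, adjusted p = 2.49e-09), and the E2F consensus TTSSCGC from 3.89% to 8.23% (odds ratio 2.21, adjusted p = 0.00386). The other 9 did not pass, including both E-boxes, the T-box, the AP-1 site and the CCAAT box. Of these, the GAGA sequence GAGAGAGA (2.84% at summits, 1.35% in flanks) passed the exact test with 100 bp to either side (odds ratio 4.08, adjusted p = 6.02e-06), with flanks 600 bp away (9.5, adjusted p = 0.000506) and without replicate 1 (2.71, adjusted p = 0.0463). The E-box CAGCTG passed with 100 bp to either side (1.79, exact test, adjusted p = 0.0476) and without replicate 1 (2.71, adjusted p = 0.0463), and the CCAAT box, rarer at summits, with 100 bp (0.763, adjusted p = 0.0476). The nuclear receptor half-site AGGTCA passed without replicate 1 (2.4, exact test, adjusted p = 0.0463) and outside promoters (3, adjusted p = 0.0453). Base composition differed along the same axis: summit windows had 50.7% GC (SD 7.37 over 668 windows), flanks 35.9% (SD 8.85) and the 6 chromosomes 35.4%. Against weaker regions of the pooled list with the same GC content, an alternative chosen after seeing the data, none of the 7 sequences passed the exact McNemar test. The SOX consensus stood at 7.04% against 9.58% (odds ratio 0.726, exact test, adjusted p = 0.486), the GATA consensus at 8.83% against 11.7% (0.708, adjusted p = 0.486), the TCF consensus at 4.04% against 4.34% (0.931, adjusted p = 1) and the E2F consensus at 8.23% against 6.74% (1.26, adjusted p = 1). The other 3 went to the other side of 1: the forkhead consensus stood at 20.8% against 16.17% (odds ratio 1.34, exact test, adjusted p = 0.486), the homeodomain core at 1.35% against 1.05% (1.33, adjusted p = 1) and the SP1/KLF box at 9.73% against 10.3% (0.933, adjusted p = 1).

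**Figure D3:**
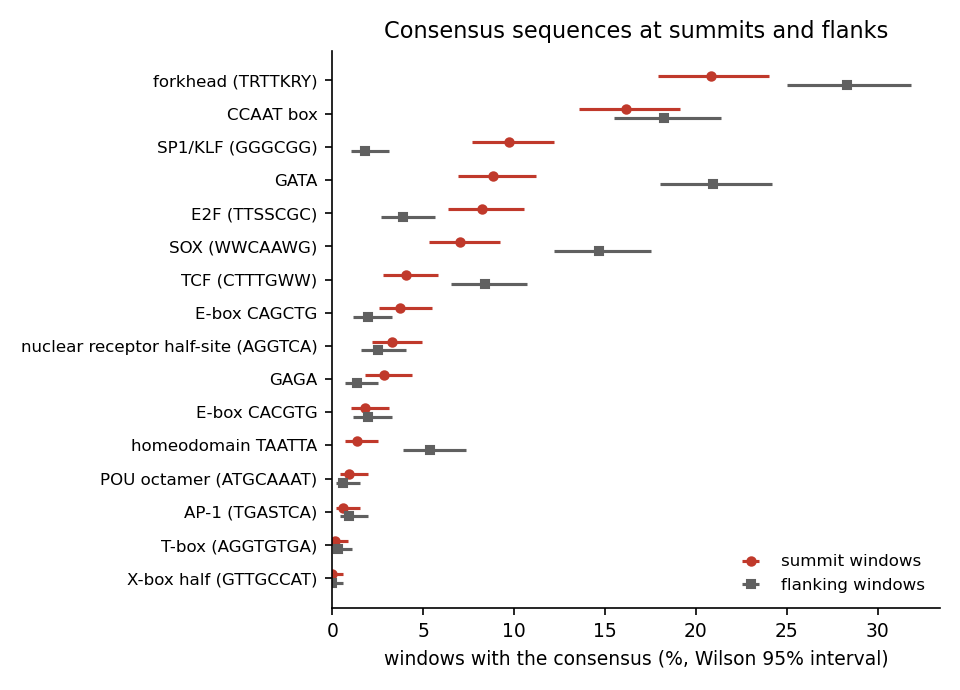
Percent of the 668 summit windows (circles) and of their flanking windows (squares) that hold each of 16 consensus sequences, with Wilson 95% intervals as horizontal bars. The SOX consensus stands at 7.04% at summits and 14.7% in flanks, and the SP1/KLF box at 9.73% and 1.80%.

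Of all 6-mers, counted with their reverse complements, 823 differed between summits and flanks at an adjusted p under 0.05 in the exact McNemar test with Benjamini-Hochberg adjustment, 456 more frequent at summits and 367 less frequent. The 5 with the smallest p were AT-rich and less frequent at summits: AAAATT in 11.8% of summit and 40.6% of flanking windows, AAAAAT in 20.5% and 47.5%, AAATTA in 5.39% and 25.9%, TTGAAA in 6.74% and 27.5%, and TTAAAA in 7.34% and 26.9%. Among 6-mers more frequent at summits, named after their values were seen, CGCACA was in 16.17% of summit and 1.65% of flanking windows, and GTTCGA in 17.2% and 3.74%. Without the peaks near tRNA, snRNA, snoRNA and microRNA genes, CGCACA stood at 21.2% against 1.93%, whereas GTTCGA stood at 3.86% against 4.34%. The internal promoter of tRNA genes, the B box, contains GTTCGA. With GC-matched weaker regions as the control, 266 6-mers passed, 139 more and 127 less frequent. Of the 5 AT-rich 6-mers above, TTGAAA passed there (6.74% against 13.3%, exact test, adjusted p = 0.00116), and the other 4 did not. AAAATT stood at 11.8% against 15.1% (exact test, adjusted p = 0.220) and AAATTA at 5.39% in both (adjusted p = 1), while AAAAAT, at 20.5% against 18.7% (adjusted p = 0.712), and TTAAAA, at 7.34% against 4.94% (adjusted p = 0.252), were on the other side. CGCACA stood at 16.17% against 4.79% and GTTCGA at 17.2% against 3.29%, both past the same exact test (adjusted p = 1.66e-09 and 1.54e-14).

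Peaks were then counted by chromosome against the share of protein-coding genes. The X chromosome held 176 peaks, 26.3% (Wilson interval 23.1 to 29.8) against 13.7% of genes, 1.93-fold (exact binomial test, adjusted p = 3.02e-17 over 6 chromosomes by Benjamini-Hochberg). By the same exact test, chromosome III held 17.2% against 13.2% (adjusted p = 0.00525), chromosome IV 12.3% against 16.43% (adjusted p = 0.00525) and chromosome V 13.0% against 25.004% (adjusted p = 7.88e-14). Chromosomes I and II held 16.3% against 14.4% and 14.8% against 17.3%, and neither passed (exact test, adjusted p = 0.168 and 0.122). Transfer RNA genes are themselves concentrated on X, which carries 276 of 612 (45.1%), and 82 of the 185 tRNA peaks (44.3%) lay there. The other 483 peaks had 94 on X, 19.5% (exact binomial p = 0.000425 against the gene share). They were not compared with the share of chromosome length, so an excess of these peaks on X is shown against the gene share only. Of the 180 promoter peaks with no RNA gene nearby, 22 (12.2%) lay on X, not above the gene share. On X lay 30 of 87 peaks near other ncRNA genes (34.5%) and 42 of 148 near no RNA gene and outside promoters (28.4%). All 55 snoRNA peaks lay on the autosomes, where 313 of the 346 snoRNA genes are.

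The strain carries extra copies of sox-4 and of unc-119, a neuronal gene used to mark transgenic worms, so both loci were examined. Around the native sox-4 gene (WBGene00015716, chromosome X, 3505270 to 3509006) 1 thresholded peak lay within 20 kb of the 5' end, where random protein-coding genes had a mean of 0.273 and a median of 0 (one-sided permutation p = 0.229). That peak was 11.99 kb away beside glt-1 (3496804 to 3497219, signal 197, rank 271). No region of the pooled list lay within 2 kb of the sox-4 5' end. Around unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935) there was no thresholded peak within 20 kb, and the best of 4 weaker regions within 2 kb ranked 7753 in the pooled list (signal 64.1). In the 668 strongest regions of a single replicate the count near sox-4 was 2 for replicate 1 (permutation p = 0.0376) and 3 for replicate 2 (permutation p = 0.00610), and near unc-119 it was 0 for both. The drawn genes came from all chromosomes, whereas sox-4 lies on X, which held more peaks than its gene share. Draws from X alone were not made, so the p-values near sox-4 may be too small.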

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

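The settings without peaks near structural RNA genes and with GC-matched weaker regions as the control were chosen after seeing the data. For the results that answer a comparison, 46 values under other settings kept their side of the threshold, or stayed within 1.5 times the main count, and 9 did not. The replicate overlap lay between 51.7% and 76.9%, the promoter ratio between 1.64 and 4.56, and the X share between 22.7% and 26.6%, all past the test. The count of 823 6-mers became 498 in the stronger 334 peaks, 500 in the 415 peaks away from structural RNA genes and 547 with 25 bp to either side, which have fewer or narrower windows by construction, and 266 with GC-matched regions, where composition is equal by construction. With GC-matched regions the SOX odds ratio was 0.726 and no longer past the threshold, nor were those of GATA (0.708), TCF (0.931) and E2F (1.26), and the odds ratio went to the other side of 1 for the forkhead consensus (1.34), the homeodomain core (1.33) and the SP1/KLF box (0.933). Of the gene lists, 0 passed with assignment within 5000 bp and 0 with background matched on distance, against 1 otherwise, and the cause was not tested. The microRNA class went from 5.95-fold to 0 when the summit had to lie inside the gene. Leaving out a replicate moved the count of regions near sox-4 from 1 to between 2 and 3. Each count was past the threshold against genes of all chromosomes, and the cause was not tested. The other results that answer a comparison kept their side without either replicate, with 705 and 792 6-mers. The 25 strongest peaks and those at every list member with a peak, not all named above, were 51 in all. Of these, 8 fell outside the strongest 668 regions of at least 1 replicate. Over single consensus sequences, RNA classes, peaks and the ribosomal list, 248 values under other settings kept their side of the threshold, 21 lost it and 8 gained it. The 4 above that had passed went to the other side of 1, as did, or reached 1, 16 of the 248, which passed in neither setting. Unknown depth limits how far the weaker peaks can be told from background.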

Other observations

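The positions of summits relative to RNA genes, the counts for RNA genes named here and the test on tRNA genes of a sequence found once were chosen only after the peaks were seen. Peaks near snoRNA genes sat just upstream of the RNA: in 49 of 55 (89.1%, Wilson interval 78.2 to 94.9) the summit lay upstream of the 5' end, at a median of 43 bp. For tRNA genes the summit was upstream in 44 of 185 (23.8%, interval 18.2 to 30.4). Every one of the 7 genes for the RNA parts of RNase P, RNase MRP and the signal recognition particle carried a peak. These were rpr-1 (I, 13463955 to 13464207, signal 592), mrpr-1 (II, 7200233 to 7200418, signal 349) and the 5 srpr genes, from srpr-2.2 (III, signal 270) to srpr-3 (V, signal 134). Genes for the SL2 spliced leader, sls-2, had a peak in 5 of 18 cases, and genes for SL1, sls-1, in 0 of 12 under this annotation. These families were not compared by a test, and the counts do not allow for reads shared between copies. Among amino acids with at least 12 tRNA genes, the share with a peak ran from 2 of 12 for tryptophan (16.7%) to 7 of 13 for cysteine (53.8%), and the 1 selenocysteine tRNA gene had none. Over all 612 tRNA genes the share was 32.2%, and differences between amino acids in these small groups were not tested.

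A gapped sequence, TGCGSCNNNNTTGC on either strand, was noticed on reading 25 summit windows of chromosome I and was then counted in all peaks. It marked 31 of the 668 peaks, 27 of them in promoters, among them atx-2 (signal 712), ears-2 (signal 663), krr-1 (signal 354), a ribosome assembly factor gene, mtss-1 (signal 313), a mitochondrial single-stranded DNA binding protein gene, rps-28 (signal 280), the translation release factor gene erfa-3 (signal 256) and the spindle checkpoint gene mdf-1 (signal 141). The sequence was in 26 of 180 promoter peaks with no RNA gene nearby (14.4%, Wilson interval 10.1 to 20.3). It was in 0 of 185 tRNA peaks (upper bound 2.03%) and in 0 of 55 snoRNA peaks (upper bound 6.53%). These counts include chromosome I, where the sequence was noticed, so the intervals do not describe a fresh sample. The split by class was not made without chromosome I. The genome held 651 matches, and those at peak summits were 4.76% of them, so most matches lay at no peak summit. Of the weaker pooled regions, 42 of 29158 held the sequence (0.144%), and of those matched on GC content 1 of 668 (0.150%). Promoters without a peak were not counted.

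For the peaks near non-coding RNA genes, a technical candidate is general background at highly transcribed small RNA genes, which would raise tRNA and snRNA genes together. Both were raised, the larger adjusted permutation p being 0.000300, so this explanation stays open, though recruitment of SOX-4-eGFP to these genes would give the same values. Reads shared between tRNA copies stay open. A peak was carried by 35.6% of 469 tRNA genes with a copied sequence and by 20.98% of 143 with a sequence found once (odds ratio 2.08, Fisher's exact p = 0.00103). Near single-copy tRNA genes alone lay 26 peaks, against 0.462 by chance and at most 4 in 10000 placements (56.3-fold). Identical full copies are not needed for these peaks, but the count cannot exclude shared reads. Copies were defined by identity over the whole gene, so a near copy counts as single-copy and may still share reads. With 1 group and no control pulldown used here, no biological explanation was tested.

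For the SOX consensus, less frequent at summits than in flanks, base composition was tested by shuffling each summit window 100 times with its dinucleotides kept. Shuffled windows held the consensus in 10.3% on average (central 95% from 8.30% to 12.9%). Composition can thus bring the flank value of 14.7% part of the way down, but the observed 7.04% lies below that range. In the 415 peaks away from structural RNA genes the values were 7.47% against 10.8% in shuffles (8.19% to 13.7%), with 13.98% in flanks. Against GC-matched weaker regions the value was 7.04% against 9.58%, and the odds ratio of 0.726 missed the threshold. A test written for an excess of the consensus, restricted to peaks outside promoters, gave an odds ratio of 0.381 and decides nothing, since there was no excess to explain.

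The same shuffles gave values for the other consensus sequences, which were not tested further. The SP1/KLF box was in 9.73% of summit windows against a shuffled mean of 5.39% (central 95% from 3.66% to 7.26%), the forkhead consensus in 20.8% against 16.3% (14.2% to 19.02%) and GAGAGAGA in 2.84% against 0.876% (0.299% to 1.58%), all above the range, although none passed against GC-matched weaker regions. The TCF consensus, whose matches are all SOX matches too, was at 4.04%, just below its range of 4.11% to 7.94%. The E2F consensus, at 8.23% against a mean of 8.84% (6.501% to 10.8%), the GATA consensus, at 8.83% (8.38% to 12.6%), and the homeodomain core, at 1.35% (0.520% to 2.096%), lay inside theirs.

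For TGCGSCNNNNTTGC, windows outside chromosome I were used, although enriched 6-mers of all chromosomes had been seen before, so they are not fully independent. There it was in 23 of 559 summit windows and 2 flanking windows (exact McNemar p = 1.94e-05). GC-rich composition alone was argued against by the spacing: 4.11% of windows (interval 2.76 to 6.10) had a gap of 4 bases, and the highest of the other gaps from 0 to 12 bases had 0.716% (interval 0.279 to 1.83). A repeat family was argued against by the 1 of 23 matches in soft-masked sequence (4.35%, interval 0.772 to 20.99). The sequence may be a binding site of a factor present at these promoters, a hypothesis found and tested on the same peaks, and whether SOX-4 or another protein binds it was not tested.

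Near sox-4 the thresholded list holds 1 peak (permutation p = 0.229), while the strongest 668 regions of replicate 1 alone hold 2 (permutation p = 0.0376) and those of replicate 2 alone hold 3 (permutation p = 0.00610). Within 10 kb the thresholded list holds 0 (permutation p = 1) and within 40 kb 2 (permutation p = 0.119). Near unc-119, also carried by the transgene, the count was 0 in all of these settings. Extra transgene copies as a source of peaks near sox-4 stay open: the thresholded list passes at none of the 3 window sizes, and how the regions of each replicate spread over the transgene was not tested. The drawn genes were not kept to X, so the single-replicate p-values cannot settle it either.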
